A study of Homo sapiens with 12 samples.

How the data were processed

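Messenger RNA was measured by sequencing in 12 libraries of AC16 cells, 3 each from control cells and from cells exposed to 0.1 µM doxorubicin for 2, 4 and 6 days, and the preparation used a NEBNext Ultra RNA kit, per the labels' protocols. The deposited values are raw counts per gene, 1 column per library, for 60607 versioned Ensembl gene IDs. Alignment and counting used fastp 0.23.2, Trimmomatic 0.38, STAR 2.7.8 and HTSeq 0.13.5 with the genome build GRCh38.p13, per the submitters' processing notes, which give no roles or order. The strand setting of the counting was not given in the sources used here, so counts of genes that overlap on opposite strands may hold reads of both. The deposited values carried no normalization, and they were whole numbers with totals of 14835743 to 21226441 per library. No library pair had counts close enough to be copies of each other. All 12 columns were used, grouped by the exposure in the labels.

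Counts were tested with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with the 4 groups, a minimum count of 10 and a minimum total of 15, which left 17320 genes, 15394 of them with a symbol and 17099 with a position in GENCODE release 29 (GRCh38). Libraries were scaled by TMM, all 12 libraries were fitted at once with a mean per group (glmQLFit with robust settings, common biological coefficient of variation 0.0887, 8 residual degrees of freedom), and each comparison was tested with glmQLFTest. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 17320 genes were counted as changed, with no minimum fold change. The 5 comparisons were each exposure against the control, day 4 against day 2 and day 6 against day 4, and a test with 3 coefficients asked for any difference among the 4 groups. The SE of a log2 fold change is its absolute value divided by the square root of F. Principal components used log2 CPM with a prior count of 2. Where a gene had 0 counts in a group, its fold change was set as a lower bound with a floor of 3 counts over that group.

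Gene lists were fixed before the data were examined: 36 lists, of which the 35 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and adjusted over the lists within a comparison. They covered p53 targets, the cell cycle, DNA replication and repair, histones, interferon, NF-kB, complement, apoptosis, senescence and stress responses. Others covered metabolism, ribosomes, mitochondria, matrix, TGF-beta, heart muscle, calcium handling, hypertrophy, and topoisomerases with anthracycline handling. The rest covered RNA quality, markers of cell types (fibroblasts among them), and globin and blood, the last with 0 members tested. The named genes followed a rule set at the same time. It took the 5 largest rises and 5 largest falls in each comparison with the control (3 and 3 in the other comparisons) among changed genes with a mean of at least 10 CPM in the higher group, no overlap between the groups and an ordinary symbol. It added up to 4 members with the smallest p of each list past the threshold, and a fixed panel of genes reported whether changed or not. For each comparison part of these were printed, with lists taken in order of p. Some genes that the rule names are not reported here.

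The alternatives were DESeq2-type size factors, library totals alone, no low-count filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, the replicate number as a block, a fit of the 2 compared groups alone and leaving out each library in turn. For the lists they also included a correlation estimated from the data and the self-contained test fry. A fit without 2 libraries that stood apart in their mitochondrial share was added after the data were seen. Shared controls were weighed with 20 simulations of unchanged groups against the same 3 controls. The procedure was tested on simulated data for day 2 against the control with 17320 genes, of which 200 were changed by set folds and 30 more were shifted together by a smaller amount as a list. It recovered 53.7% of 1.5-fold, 92.5% of 2-fold and 98.5% of 4-fold changes, and 17 of 198 calls (8.59%) were false, above the 5% that the threshold aims at. The other calls were 163 of the 200 genes and 18 of the 30.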

Results

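The series measured messenger RNA in AC16 cells, a human line made by fusing ventricular cells of the adult heart with transformed fibroblasts, after exposure to doxorubicin, an anthracycline that traps topoisomerase II on broken DNA. The stated question was how the response changes with the length of exposure, in the setting of doxorubicin-induced heart damage and hypertrophy. There were 12 libraries in 4 groups of 3: control cells in medium, and cells given 0.1 µM doxorubicin for 2, 4 or 6 days. The titles give the exposures as 48, 96 and 112 hours and day 6 for every library, so the longest exposure is 6 days in the series design and 112 hours in the titles. The labels place the exposures before harvest but do not say whether each ended at harvest, so cells with a shorter exposure may have been sampled some time after the drug was removed. Day 2, day 4 and day 6 therefore name lengths of exposure in separate groups. Total counts lay between 14835743 and 21226441 per library, and 17320 genes were tested. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels are normalised CPM given as mean ± SD (n = 3), and log2 fold changes are given ± SE.

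The 4 groups lay apart from each other in the expression of all tested genes. Controls had scores of -67.9 to -65.5 on the first principal component, which held 40.8% of the variance, and all 9 treated libraries had scores of 11 to 28.4. The second component, with 25.8% of the variance, set the day 2 libraries (46.9 to 49.7) apart from the day 4 (-22.8 to -16.6) and day 6 libraries (-33 to -30.8). Across the whole course 10978 genes differed between groups, which was 63.4% of those tested. Among these, the highest group mean was in the control for 3663 genes, at day 2 for 3691, at day 4 for 1152 and at day 6 for 2472.

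**Figure D1:**
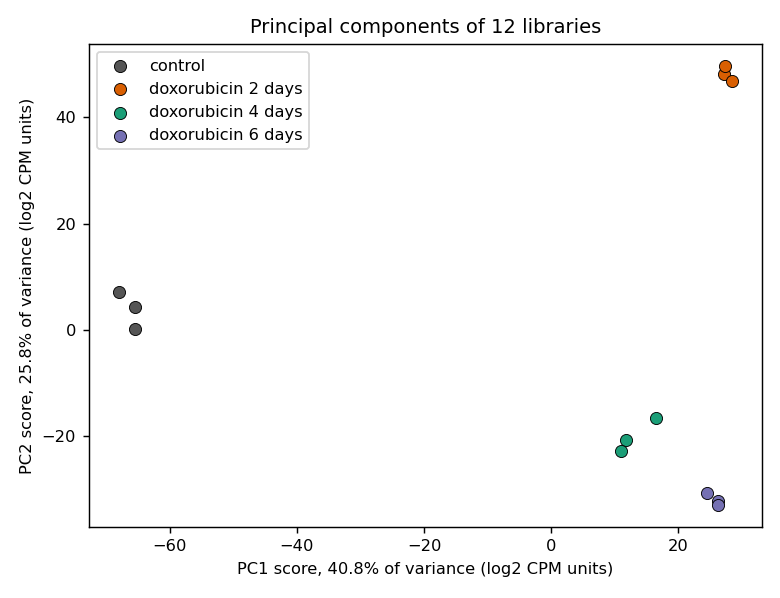
Scores of the 12 libraries on the first and second principal components of log2 CPM over 17320 genes, with 1 point per library and 1 colour per group. The 3 controls sit at -67.9 to -65.5 on the first component, and the day 2 libraries at 46.9 to 49.7 on the second.

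The question of what 2 days of doxorubicin changed had its clearest answer in genes of the p53 response, which halts the cell cycle and can trigger cell death after DNA damage. All 34 tested p53 targets rose. CDKN1A, which encodes the cell-cycle inhibitor p21 (GRCh38 chromosome 6, 36676460 to 36687339, ENSG00000124762.14), rose from 198 ± 31.4 to 2300 ± 228 CPM, a log2 fold change of 3.54 ± 0.11 (adjusted p = 3.93e-18). MDM2, a ubiquitin ligase gene of the same list (chromosome 12, 68808176 to 68850686), rose from 162 ± 14.6 to 2227 ± 225 CPM. Genes of mitosis fell over the same interval, 42 of 46 tested, and LMNB1, the gene for lamin B1 of the nuclear envelope (chromosome 5, 126776623 to 126837020), fell from 224 ± 7.88 to 51.2 ± 5.83 CPM (4.38-fold lower, adjusted p = 8.98e-16).

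In total 8180 genes changed at day 2, 4122 of them higher and 4058 lower, and of these 1432 were at least 2-fold higher and 923 at least 2-fold lower. Scaling by library totals alone moved the median of all genes to -0.136 on the log2 scale and the split to 3203 higher and 5386 lower, so directions are relative to that scaling. The groups did not overlap for 52.2% of genes, where chance gives 10%. The largest rises included a pair of peptidylarginine deiminases, PADI4 (ENSG00000159339.13, chromosome 1, 17308195 to 17364004), from 0.0848 ± 0.0412 to 11.5 ± 1.72 CPM, and its neighbour PADI3 (chromosome 1, 17249098 to 17284233), from 0.126 ± 0.133 to 11.5 ± 1.21 CPM (log2 fold change 6.44 ± 0.35, and 7.4 without control replicate 3). AKR1B10, an aldo-keto reductase, rose by 5.73 ± 0.34 on the log2 scale (6.33 without control replicate 2). GDF15, a stress cytokine, rose from 2.85 ± 0.728 to 130.2 ± 15.7 CPM. IL1A, an interleukin, rose from 0.777 ± 0.448 to 34.0 ± 1.29 CPM. INHBE, which encodes an activin subunit, fell the furthest, from 14.1 ± 3.32 to 0.460 ± 0.300 CPM (28.7-fold lower; log2 fold change -4.84 ± 0.30, and -5.57 without day 2 replicate 1), followed by GUCY1A2 (-2.98 ± 0.35), VASH2 (-2.36 ± 0.18) and the interleukin-33 receptor gene IL1RL1 (-2.20 ± 0.25).

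The p53 list (adjusted p = 1.06e-35, median log2 fold change 2.25) had its smallest p-values in TP53I3 (4.54 ± 0.11), BTG2 (4.41 ± 0.12) and CYFIP2 (4.46 ± 0.13) beside MDM2, and the same 34 rose adjusted over the list alone. In the mitosis and G2/M list 0 of 46 tested members rose and 42 fell (0 and 42 adjusted over the list alone), with a median log2 fold change of -0.81 and an adjusted p of 4.82e-22. CCNA2 and CCNB1, the cyclins that drive entry into mitosis, fell by 1.27 and 1.25 on the log2 scale. TOP2A, the topoisomerase of dividing cells, fell from 961 ± 35.9 to 425 ± 14.2 CPM, and the kinesin KIF23 and the proliferation marker MKI67 fell as well (-1.05 ± 0.072 and -1.13 ± 0.083). For DNA replication and S phase, 2 of 45 tested members rose and 33 fell (2 and 33 adjusted over the list alone), with a median log2 fold change of -0.53 and an adjusted p of 2.22e-10 (adjusted p = 0.108 with an estimated correlation). CLSPN, RRM2, MCM6 and CCNE2 fell by 1.31, 1.12, 1.27 and 2.06. Homologous recombination and Fanconi genes fell too. In that list 2 of 33 rose and 23 fell (2 and 23 adjusted over the list alone, adjusted p = 2.28e-07, and adjusted p = 0.0903 with an estimated correlation), led by RAD51AP1 (-1.26 ± 0.093) and FANCA (-1.08 ± 0.081).

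Interferon-stimulated genes, which cells switch on against viruses and cytosolic nucleic acid, rose at day 2, with TRIM22 going from 11.8 ± 1.45 to 129.6 ± 1.89 CPM and OASL from 1.67 ± 0.497 to 56.4 ± 7.38 CPM. Of this list, 33 of 43 tested members rose and 0 fell (34 and 0 adjusted over the list alone), with a median log2 fold change of 1.31 and an adjusted p of 1.22e-14, and IFI44 and HERC5 rose by 2.26 and 1.88. Genes of the NF-kB and secretory list, which holds inflammatory cytokines and also genes of proteins that are not secreted, rose with them. In that list 26 of 41 tested members rose and 2 fell (26 and 2 adjusted over the list alone), with a median log2 fold change of 1.42 and an adjusted p of 3.73e-13. IL1B rose from 36.8 ± 6.02 to 646 ± 17.5 CPM and the NF-kB inhibitor gene TNFAIP3 by 3.47 ± 0.12. The chemokine gene CXCL8 rose from 14.1 ± 1.41 to 95.8 ± 4.81 CPM, BIRC3 by 3.01 ± 0.11, and IL6 from 26.0 ± 3.59 to 162 ± 14.3 CPM. Among complement and coagulation genes 14 of 24 rose and 3 fell (14 and 3 adjusted over the list alone, adjusted p = 0.000327). C3, the central complement protein, rose from 2.93 ± 0.598 to 112 ± 7.02 CPM and F3, the tissue factor gene, by 2.13 ± 0.088.

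Matrix and contractile genes of mesenchymal cells also rose at day 2. In the list of extracellular matrix and fibrosis genes 26 of 37 tested members rose and 5 fell (27 and 5 adjusted over the list alone), with a median log2 fold change of 0.72 and an adjusted p of 1.25e-07, with POSTN (1.74 ± 0.084), COL5A1 (1.37 ± 0.074), TGFBI (1.44 ± 0.078) and COL4A1 (1.51 ± 0.084) leading. COL1A1 rose from 2582 ± 235 to 4529 ± 217 CPM. Smooth muscle and myofibroblast markers rose in 10 of 12 cases and fell in 0 (10 and 0 adjusted over the list alone, adjusted p = 1.7e-07), among them ACTA2 from 10.1 ± 2.03 to 83.4 ± 4.36 CPM and MYOCD by 1.39 ± 0.091. Of TGF-beta response genes 17 of 28 rose and 3 fell (19 and 3 adjusted over the list alone, adjusted p = 2.67e-06). INHBA rose by 2.84 ± 0.091. Epithelial markers moved with them, as 6 of 9 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.000581, and adjusted p = 0.13 with an estimated correlation), and the keratin KRT17 reached 17.5 ± 1.67 CPM from 1.51 ± 0.535. Fibroblast markers were not past the threshold (9 of 16 rose and 1 fell, adjusted p = 0.0513).

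Smaller shifts at day 2 touched metabolism and cell death. Among glycolysis and hypoxia genes 23 of 33 rose and 2 fell (25 and 2 adjusted over the list alone, adjusted p = 3.04e-06, and adjusted p = 0.317 with an estimated correlation), including VEGFA (1.36 ± 0.10) and NDRG1 (2.27 ± 0.16). For apoptosis genes 24 of 41 rose and 6 fell (24 and 6 adjusted over the list alone, adjusted p = 8.01e-06). The death receptor genes FAS and TNFRSF10B rose by 3.25 and 1.65. Cholesterol biosynthesis genes fell, as 2 of 25 rose and 17 fell (2 and 17 adjusted over the list alone, adjusted p = 1.14e-05), and INSIG1 dropped from 620.2 ± 20.9 to 160.4 ± 19.0 CPM. The lists of nuclear-encoded oxidative phosphorylation genes (21 of 54 rose and 3 fell, 21 and 3 adjusted over the list alone) and cytosolic ribosomal proteins (13 of 72 rose and 3 fell, 6 and 1 adjusted over the list alone) were past the threshold with medians of 0.18 and 0.13 (adjusted p = 0.0393 and 0.0248, and adjusted p = 0.767 and 0.88 with an estimated correlation). Both calls ended without control replicate 1 (adjusted p = 0.211 and 0.294), control replicate 3 (0.103 and 0.189) or day 2 replicate 1 (0.137 and 0.134), that of oxidative phosphorylation also with a minimum of 1 CPM in 3 libraries (0.057), and that of the ribosomal proteins also without day 2 replicate 2 (0.0811).

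Cardiac genes gave a mixed picture at day 2. NPPB, the natriuretic peptide gene used as a marker of cardiac strain, rose from 0.852 ± 0.112 to 7.68 ± 1.99 CPM (adjusted p = 2.45e-08) and ANKRD1, a stress-induced cardiac ankyrin gene, from 6.97 ± 1.48 to 30.1 ± 8.32 CPM. NPPA stayed below 1 CPM in every group mean. Its fall from 0.645 ± 0.365 to 0.148 ± 0.1298 CPM (adjusted p = 0.0421) was no longer past the threshold without control replicate 1 (adjusted p = 0.0826), control replicate 3 (0.159), day 2 replicate 1 (0.17) or day 2 replicate 2 (0.0627). Its log2 fold change of -2.16 ± 0.86 was -1.49 without day 2 replicate 1 and -2.76 without day 2 replicate 3. The hypertrophy and fetal-program list was not past the threshold (13 of 30 rose and 9 fell, 15 and 9 adjusted over the list alone, adjusted p = 0.215), and neither was the sarcomere list (6 of 13 rose and 1 fell, adjusted p = 0.0866). Of the 34 members of the sarcomere list only 13 were tested, so its results do not cover the others. Over the 3 libraries of a group MYH7 had 0, 1, 4 and 3 counts from the control to day 6. ACTA1 had 16, 4, 2 and 7, ACTC1 12, 9, 4 and 5, and TNNT2 12, 2, 0 and 3. MYL2 had 0 counts in every library. TOP2B, the topoisomerase of non-dividing heart cells, had a log2 fold change of -0.20 ± 0.082 (adjusted p = 0.0502) and HMOX1, the heme oxygenase gene, one of -0.11 ± 0.11 (adjusted p = 0.461).

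**Figure D2:**
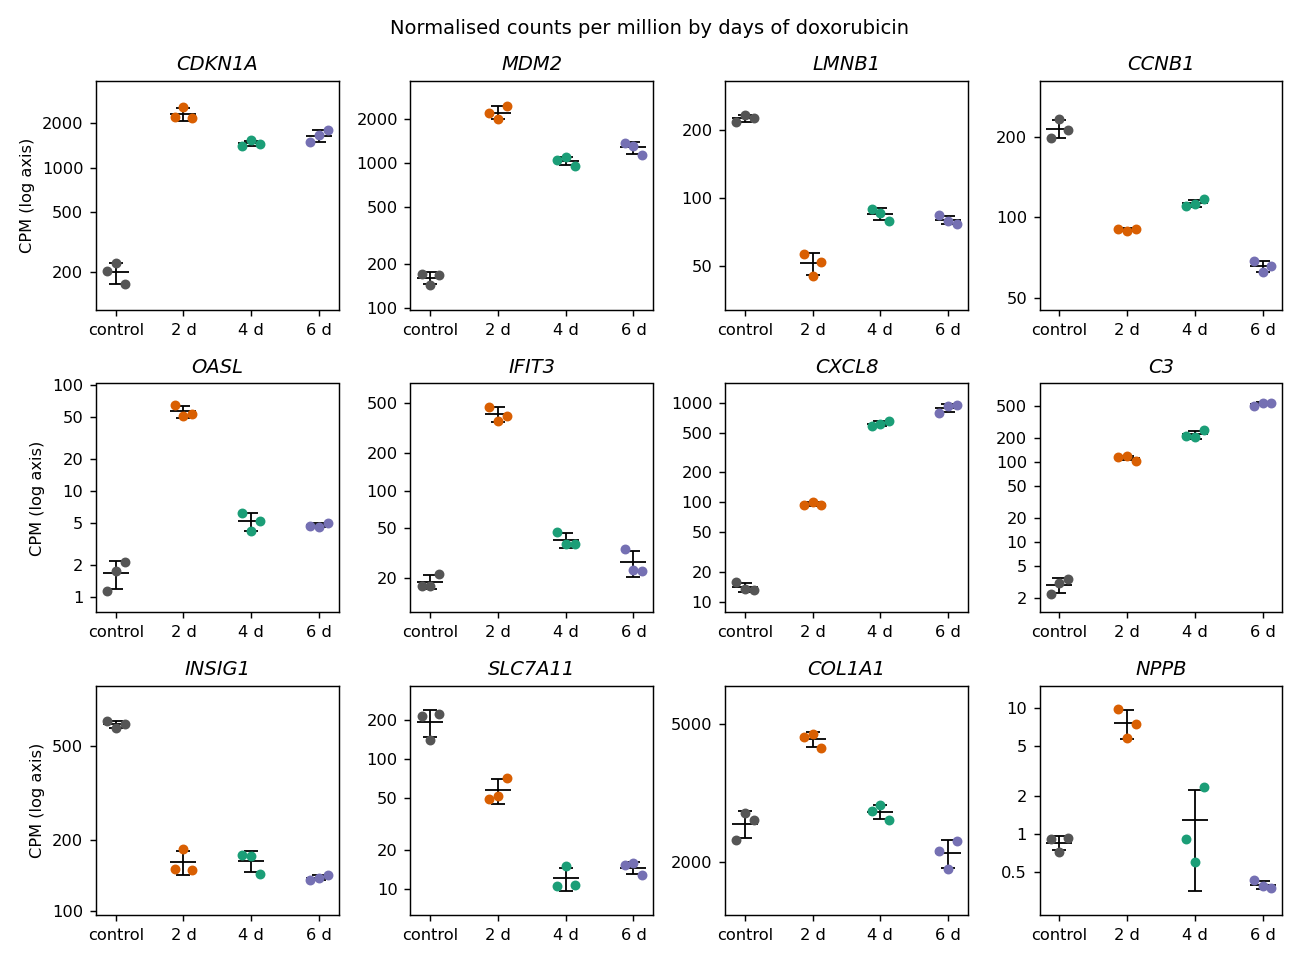
Normalised CPM (log axis) of 12 genes in the control and after 2, 4 and 6 days (d) of doxorubicin, with 1 point per library, a horizontal line at the mean and bars of 1 SD (n = 3). CDKN1A and MDM2 stay high at every exposure, OASL and IFIT3 peak at day 2, and CXCL8 and C3 are highest at day 6, at 882 and 533 CPM.

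Among genes above 10 CPM, the highest rises after 4 days were in genes of secreted immune proteins. CSF2, which encodes the growth factor GM-CSF (chromosome 5, 132073790 to 132076170), had 0 counts in the 3 controls and 40.0 ± 13.01 CPM at day 4, at least 645-fold higher against a floor of 3 counts over the control group. CSF3, the gene of G-CSF, rose from 0.0757 ± 0.131 to 14.7 ± 0.613 CPM. Only control replicate 1 held counts of CSF3, so the log2 fold change of 7.34 ± 0.36 rests on that library, and no fold is given without it. CXCL1 rose from 0.540 ± 0.132 to 50.1 ± 3.51 CPM and C3 (ENSG00000125730.17, chromosome 19, 6677704 to 6730562) from 2.93 ± 0.598 to 220.3 ± 26.2 CPM (adjusted p = 1.78e-21). CXCL8 rose to 616 ± 34.5 CPM (43.7-fold higher, adjusted p = 4.15e-22). In the NF-kB and secretory list 32 of 41 tested members rose and 1 fell (34 and 2 adjusted over the list alone), with a median log2 fold change of 1.43 and an adjusted p of 2.77e-23, and IL1B and IL6 reached 899.6 ± 61.7 and 188 ± 16.6 CPM.

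At day 4 there were 6321 changed genes, 3249 higher and 3072 lower, with 958 and 618 at least 2-fold higher and lower. Scaling by library totals alone gave 2913 higher and 3458 lower. The groups did not overlap for 44.6% of genes, where chance gives 10%. SERPINA9, a serpin, rose by 5.73 ± 0.46. The furthest falls were in INHBE (-5.26 ± 0.31) and in SLC7A11, which encodes the cystine transporter that feeds glutathione synthesis (ENSG00000151012.13, chromosome 4, 138164097 to 138242349), from 196 ± 46.5 to 12.0 ± 2.45 CPM. They were followed by HES1, a Notch target (-3.07 ± 0.20), PDGFD (-3.01 ± 0.18) and OLFML3 (-2.73 ± 0.17). The p53 targets stayed high: 31 of 34 tested members rose and 1 fell (32 and 1 adjusted over the list alone), with a median log2 fold change of 1.82 and an adjusted p of 2.34e-32. MDM2, CDKN1A, CYFIP2 and TP53I3 rose by 2.67, 2.88, 3.53 and 2.79, and GDF15 by 4.05 ± 0.16.

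Cell-cycle genes were lower than in the control at day 4. For mitosis and G2/M 0 of 46 tested members rose and 38 fell (0 and 40 adjusted over the list alone), with a median log2 fold change of -0.60 and an adjusted p of 1.32e-20. KIF20A, CCNB1 and KIF23 fell by 1.56, 0.92 and 0.82. MKI67 fell to 601 ± 48.0 CPM, TOP2A to 667 ± 34.5 and LMNB1 to 84.6 ± 5.30. For DNA replication and S phase 5 of 45 rose and 29 fell (5 and 30 adjusted over the list alone, adjusted p = 2.41e-06, and adjusted p = 0.233 with an estimated correlation), including MCM6 (-1.15 ± 0.090) and UHRF1 (-0.83 ± 0.083). Homologous recombination and Fanconi genes followed, as 1 of 33 rose and 14 fell (1 and 14 adjusted over the list alone, adjusted p = 0.00126, and adjusted p = 0.248 with an estimated correlation), and EXO1 fell by 0.70. Of replication-dependent histones 0 of 21 rose and 10 fell (0 and 12 adjusted over the list alone, adjusted p = 0.00218, and adjusted p = 0.0737 with an estimated correlation), among them H1-2, from 13.5 ± 0.939 to 6.69 ± 2.15 CPM. Histone genes are near copies of each other, so reads of 1 member may be counted for another. Only 21 of the 58 members of that list were tested, so its results do not cover the others. In ribosome biogenesis 0 of 30 rose and 16 fell (0 and 16 adjusted over the list alone, adjusted p = 3.1e-05, and adjusted p = 0.228 with an estimated correlation), including MYC, the growth regulator, from 132 ± 10.7 to 50.0 ± 5.37 CPM, and the nucleolar genes FBL and NOLC1 (-0.78 ± 0.094 and -0.50 ± 0.073).

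Cholesterol genes and genes of the ATF4 list were lower at day 4 than in the control. In cholesterol biosynthesis 0 of 25 tested members rose and 20 fell (1 and 20 adjusted over the list alone), with a median log2 fold change of -0.79 and an adjusted p of 5.52e-15. INSIG1 was at 163 ± 16.5 CPM, and HMGCS1, an early enzyme of the pathway, fell from 469.5 ± 45.7 to 167 ± 10.7 CPM. In the ATF4 and unfolded protein list 7 of 38 tested members rose and 22 fell (8 and 22 adjusted over the list alone), with a median log2 fold change of -0.45 and an adjusted p of 1.46e-07. In that list the serine enzyme gene PSAT1 fell from 325 ± 7.37 to 66.1 ± 4.24 CPM, the transporter gene SLC7A5 from 441 ± 9.17 to 119.7 ± 13.3 CPM, and TRIB3 and SHMT2 by 2.44 ± 0.11 and 1.52 ± 0.087. Genes of the NRF2 and oxidative stress list fell in 18 of 39 cases and rose in 8 (20 and 8 adjusted over the list alone, adjusted p = 0.0131, and adjusted p = 0.248 with an estimated correlation), including NQO1, from 129 ± 4.42 to 55.5 ± 1.42 CPM, and the gene of NRF2 itself, NFE2L2 (-0.84 ± 0.069). The topoisomerase and anthracycline handling list fell, as 2 of 23 rose and 12 fell (2 and 13 adjusted over the list alone, adjusted p = 0.000242). AKR1C3, an enzyme that reduces doxorubicin, went from 48.7 ± 3.52 to 9.19 ± 1.303 CPM. HMOX1 fell to 11.1 ± 0.931 CPM.

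Other groups rose by less at day 4. Glycolysis and hypoxia genes rose in 23 of 33 cases and fell in 2 (24 and 2 adjusted over the list alone, adjusted p = 4.39e-06, and adjusted p = 0.284 with an estimated correlation), such as VEGFA (1.16 ± 0.10) and ENO2 (0.81 ± 0.087). For complement and coagulation 15 of 24 rose and 6 fell (15 and 6 adjusted over the list alone, adjusted p = 0.000242). PLAT, the plasminogen activator gene, rose from 239 ± 14.6 to 1200 ± 199.7 CPM. For interferon-stimulated genes 17 of 43 rose and 4 fell (19 and 5 adjusted over the list alone, adjusted p = 0.00428, and adjusted p = 0.228 with an estimated correlation). The list median was 0.395, against 1.31 at day 2, while TRIM22 stayed at 106 ± 16.1 CPM and so does not stand for the list. For apoptosis 18 of 41 rose and 6 fell (19 and 7 adjusted over the list alone, adjusted p = 0.00443, and adjusted p = 0.118 with an estimated correlation). For autophagy and lysosome 16 of 38 rose and 5 fell (18 and 6 adjusted over the list alone, adjusted p = 0.0295, and adjusted p = 0.3 with an estimated correlation). CTSB rose by 0.70 ± 0.075. Smooth muscle and myofibroblast markers rose in 6 of 12 cases and fell in 3 (6 and 3 adjusted over the list alone, adjusted p = 0.0336, and adjusted p = 0.132 with an estimated correlation), and ACTA2 reached 94.7 ± 1.80 CPM. The nuclear-encoded oxidative phosphorylation list rose in 16 of 54 cases and fell in 2 (16 and 2 adjusted over the list alone, adjusted p = 0.00819, and adjusted p = 0.53 with an estimated correlation). The mitochondrially encoded list rose in 5 of 13 cases and fell in 0 (6 and 0 adjusted over the list alone, adjusted p = 0.0191, and adjusted p = 0.53 with an estimated correlation), with MT-CO1 at 16750 ± 383 CPM against 11650 ± 1610.

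Without control replicate 1 the day 4 calls ended for the lists of autophagy (adjusted p = 0.0618), smooth muscle (0.0576), mitochondrially encoded (0.131) and oxidative phosphorylation genes (0.084). The same held for autophagy without control replicate 3 (adjusted p = 0.0786) and for the NRF2 list without control replicate 2 (0.0652). NPPB, at 1.29 ± 0.941 CPM, was not past the threshold (adjusted p = 0.255), nor were NPPA (0.391, and 0.0448 without day 4 replicate 3), TOP2B (0.118) and COL1A1, at 2794 ± 133 CPM (0.317), while ANKRD1 was still raised at 14.2 ± 3.48 CPM (0.00142). Matrix genes (21 of 37 rose and 11 fell, 22 and 11 adjusted over the list alone, adjusted p = 0.0555) and hypertrophy genes (7 of 30 rose and 11 fell, 7 and 12 adjusted over the list alone, adjusted p = 0.0523) were not past the threshold as lists.

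At the longest exposure secreted immune genes stayed high, C3 and CXCL8 stood above their day 4 level, and mitotic genes stood lower. CSF2 reached 42.5 ± 3.42 CPM, at least 675-fold above the controls, and EHF, an epithelial transcription factor gene (ENSG00000135373.13, chromosome 11, 34621093 to 34661057), which also had 0 counts in the controls, reached 15.7 ± 0.732 CPM, at least 251-fold higher. C3 rose to 533 ± 23.8 CPM (183-fold, adjusted p = 3.67e-23) and CXCL8 to 882 ± 80.1 CPM (62.6-fold, adjusted p = 3.67e-23). In mitosis and G2/M 0 of 46 tested members rose and 44 fell (0 and 44 adjusted over the list alone), with a median log2 fold change of -1.02 and an adjusted p of 3.4e-32. KIF20A, a kinesin of cell division, fell from 159 ± 12.1 to 29.9 ± 2.33 CPM.

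At day 6 there were 7571 changed genes, 3810 higher and 3761 lower, with 1342 and 797 at least 2-fold higher and lower, and 50.9% of genes did not overlap between the groups, where chance gives 10%. CSF3 reached 24.6 ± 5.41 CPM (log2 fold change 8.09 ± 0.34, again resting on control replicate 1). PINCR, a long non-coding RNA, rose from 0.110 ± 0.101 to 10.2 ± 0.973 CPM (log2 fold change 6.51 ± 0.34, 5.89 without control replicate 1 and 7.23 without control replicate 3). INHBE, SLC7A11, OLFML3, HES1 and ERBB3, a receptor of neuregulins, fell furthest, by 5.52, 3.76, 3.15, 3.12 and 2.88. For p53 targets 31 of 34 tested members rose and 1 fell (31 and 1 adjusted over the list alone), with a median log2 fold change of 2.03 and an adjusted p of 3.43e-29. CYFIP2, TP53I3, MDM2 and CDKN1A rose by 4.34, 3.34, 2.98 and 3.06, and GDF15 was at 61.2 ± 10.2 CPM. For NF-kB and secretory genes 33 of 41 tested members rose and 3 fell (33 and 3 adjusted over the list alone), with a median log2 fold change of 1.51 and an adjusted p of 3.32e-20. IL1B stood at 1060 ± 85.7, IL6 at 293 ± 22.8 and CXCL1 at 45.3 ± 2.01 CPM.

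CCNB1 was at 65.7 ± 3.00 CPM, CCNA2 at 53.4 ± 1.29, MKI67 at 405 ± 22.9, TOP2A at 477 ± 18.4 and LMNB1 at 79.8 ± 3.35, all below the control. For DNA replication and S phase 6 of 45 rose and 20 fell (7 and 21 adjusted over the list alone, adjusted p = 0.00767, and adjusted p = 0.52 with an estimated correlation). UHRF1 and MCM6 were lower (-0.89 ± 0.083 and -0.78 ± 0.089). The recombination and Fanconi list was not past the threshold (5 of 33 rose and 11 fell, adjusted p = 0.406). Replication-dependent histones fell, as 0 of 21 rose and 11 fell (0 and 11 adjusted over the list alone, adjusted p = 0.00393, and adjusted p = 0.0797 with an estimated correlation). H1-2 stood at 3.59 ± 0.801 CPM. In ribosome biogenesis 0 of 30 rose and 18 fell (0 and 18 adjusted over the list alone, adjusted p = 4.31e-05, and adjusted p = 0.249 with an estimated correlation). MYC stood at 49.5 ± 9.25 CPM and DDX21 was lower (-0.75 ± 0.073). In cholesterol biosynthesis 1 of 25 tested members rose and 20 fell (1 and 20 adjusted over the list alone), with a median log2 fold change of -1.05 and an adjusted p of 2.63e-13. INSIG1 stood at 138 ± 3.19 CPM. In the ATF4 list 7 of 38 rose and 22 fell (7 and 22 adjusted over the list alone, adjusted p = 8.83e-07, and adjusted p = 0.064 with an estimated correlation). SLC7A5 stood at 75.2 ± 5.63 and TRIB3 at 14.9 ± 0.562 CPM.

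Further groups were past the threshold at day 6. Of glycolysis and hypoxia genes 20 of 33 rose and 2 fell (20 and 2 adjusted over the list alone, adjusted p = 0.00363, and adjusted p = 0.544 with an estimated correlation). Of complement and coagulation genes 12 of 24 rose and 6 fell (12 and 6 adjusted over the list alone, adjusted p = 0.00393). Among apoptosis genes 18 of 41 rose and 4 fell (19 and 4 adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.154 with an estimated correlation). Among interferon-stimulated genes 18 of 43 rose and 5 fell (19 and 7 adjusted over the list alone, adjusted p = 0.0185, and adjusted p = 0.32 with an estimated correlation). The median log2 fold changes of these 4 lists were 0.282, 0.348, 0.225 and 0.264. The members named by their small p lay far above these medians: VEGFA (1.53 ± 0.10), TFPI2 (2.01 ± 0.10), FAS (2.26 ± 0.11) and TRIM22 (3.35 ± 0.11). On the falling side stood the topoisomerase and anthracycline handling list, where 3 of 23 rose and 10 fell (4 and 10 adjusted over the list alone, adjusted p = 0.0185, and adjusted p = 0.0797 with an estimated correlation). It also held the NRF2 list, where 10 of 39 rose and 18 fell (10 and 20 adjusted over the list alone, adjusted p = 0.0239, and adjusted p = 0.332 with an estimated correlation). NQO1 stood at 44.99 ± 1.80 and AKR1C3 at 8.50 ± 0.971 CPM. Heat shock genes fell, as 1 of 21 rose and 13 fell (1 and 13 adjusted over the list alone, adjusted p = 0.0228, and adjusted p = 0.487 with an estimated correlation). HSP90AA1 went from 2613 ± 329.6 to 1808 ± 84.2 CPM. Fibroblast markers fell, as 4 of 16 rose and 9 fell (4 and 9 adjusted over the list alone, adjusted p = 0.0479, and adjusted p = 0.246 with an estimated correlation). LUM, the lumican gene, went from 213 ± 7.42 to 58.8 ± 4.45 CPM and DCN from 126 ± 2.94 to 64.5 ± 4.32. The fibroblast call ended without control replicate 3 (adjusted p = 0.0622), without day 6 replicate 2 (0.0619) and with a minimum of 1 CPM in 3 libraries (0.0898), and the heat shock and NRF2 calls without control replicate 2 (0.0614 and 0.0791).

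NPPB and ANKRD1, raised at day 2, were not past the threshold at day 6. NPPB was at 0.393 ± 0.0297 CPM (adjusted p = 0.0714) and ANKRD1 at 8.97 ± 0.714 CPM (adjusted p = 0.216). TOP2B fell to 169 ± 9.90 CPM (adjusted p = 0.000548) and HMOX1 to 10.9 ± 0.505 CPM (adjusted p = 7.39e-05). COL1A1 fell to 2127 ± 197 CPM (adjusted p = 0.00954, and 0.0837 without day 6 replicate 2). NPPA, at 0.114 ± 0.116 CPM, fell (adjusted p = 0.0306), a call that ended without control replicate 1 (0.063), control replicate 3 (0.127), day 6 replicate 1 (0.0989) or day 6 replicate 2 (0.082). Its log2 fold change of -2.33 ± 0.85 was -3.33 without day 6 replicate 3. The sarcomere list (5 of 13 rose and 4 fell, adjusted p = 0.798), the hypertrophy list (7 of 30 rose and 13 fell, 9 and 14 adjusted over the list alone, adjusted p = 0.0558) and the matrix list (17 of 37 rose and 12 fell, 17 and 13 adjusted over the list alone, adjusted p = 0.593) were not past the threshold.

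**Figure D3:**
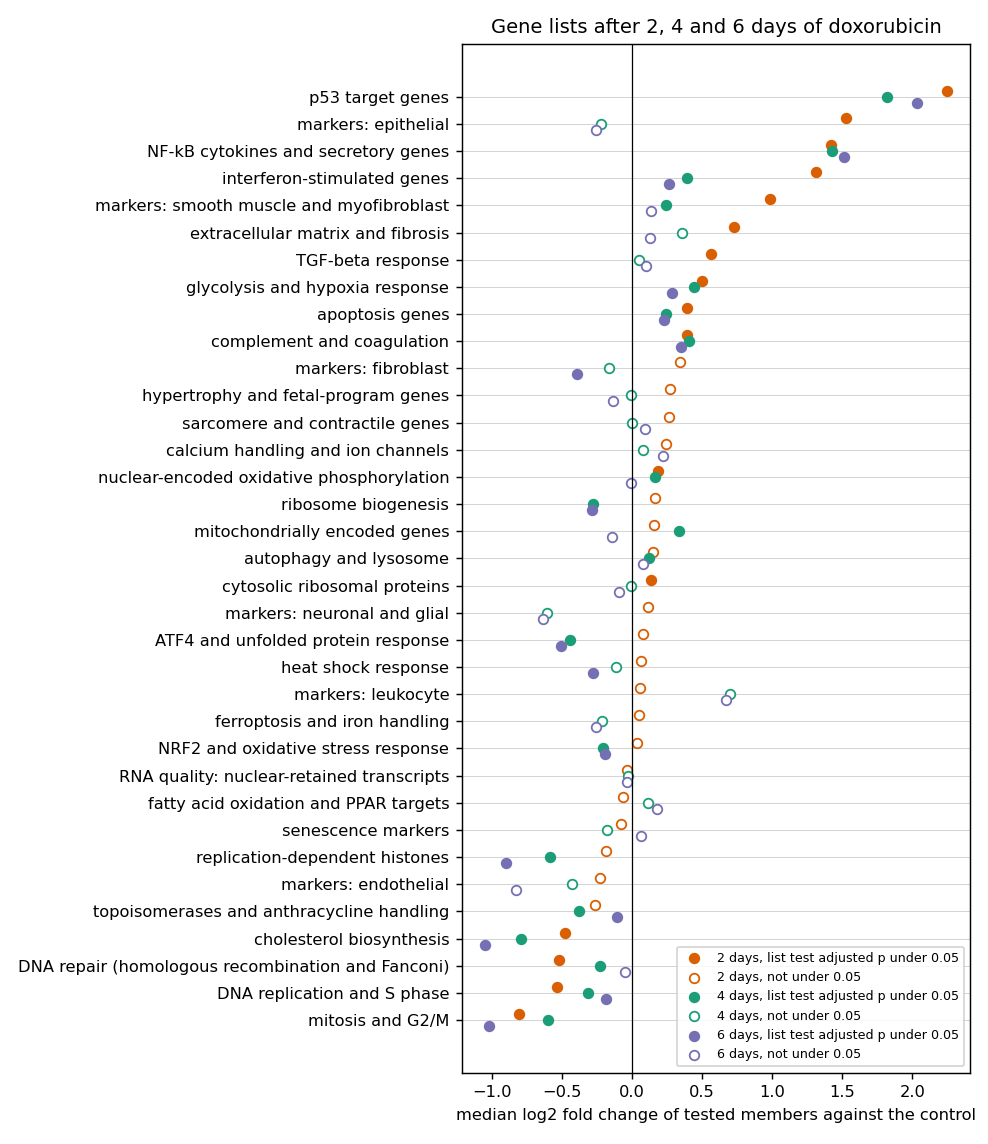
Median log2 fold change against the control of the tested members of 35 gene lists after 2, 4 and 6 days of doxorubicin, with filled points for lists whose test gave an adjusted p under 0.05. The p53 targets have the highest medians (2.25, 1.82 and 2.03), and the medians of 6, 1 and 2 lists without a call change sign under another scaling.

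The comparison of day 4 with day 2 asked what differed between the longer and the shorter exposure, and interferon-stimulated genes were lower after the longer one. IFIT3 (chromosome 10, 89327894 to 89340971) went from 411 ± 54.8 to 40.3 ± 5.52 CPM (10.2-fold lower, adjusted p = 6.79e-11), IFIT2 from 273 ± 34.7 to 28.2 ± 3.14 CPM and OASL from 56.4 ± 7.38 to 5.19 ± 1.01 CPM. Of the whole list 0 of 43 tested members rose and 32 fell (0 and 33 adjusted over the list alone), with a median log2 fold change of -0.94 and an adjusted p of 1e-15. Some cytokine genes went the other way, as CXCL8 rose by 2.69 ± 0.088 (adjusted p = 1.56e-16), CSF3 by 4.49 ± 0.25, CSF2 by 3.53 ± 0.25 and CXCL1 by 2.50 ± 0.12.

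There were 6031 genes that differed, 2828 higher and 3203 lower at day 4, with 506 and 744 at least 2-fold higher and lower, and 45.9% of genes did not overlap, where chance gives 10%. Scaling by library totals alone gave 3842 higher and 2443 lower. MIR3142HG, the host gene of a microRNA, rose by 3.45 ± 0.22, and its counts may hold reads of a gene on the other strand. For NF-kB and secretory genes 19 of 41 tested members rose and 14 fell (20 and 14 adjusted over the list alone), with a median log2 fold change of 0.21 and an adjusted p of 0.0159 (adjusted p = 0.283 with an estimated correlation). The p53 targets were lower than at day 2 while most stayed above the control, as 1 of 34 tested members rose and 29 fell (1 and 30 adjusted over the list alone), with a median log2 fold change of -0.78 and an adjusted p of 2.09e-17. TP53I3, PPM1D, CMBL and BTG2 fell by 1.75, 1.27, 1.37 and 1.37, MDM2 by 1.11, CDKN1A by 0.66 and GDF15 by 1.46. Apoptosis genes fell in 15 of 41 cases and rose in 1 (18 and 2 adjusted over the list alone, adjusted p = 0.000944, and adjusted p = 0.0526 with an estimated correlation), with FAS and BAK1 down by 1.19 and 1.04.

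Some cell-cycle genes were higher at day 4 than at day 2. For mitosis and G2/M 25 of 46 rose and 5 fell (26 and 5 adjusted over the list alone, adjusted p = 0.000107). CDK1, the mitotic kinase gene, went from 108 ± 6.77 to 174 ± 7.35 CPM and TOP2A rose by 0.65 ± 0.072. For DNA replication 18 of 45 rose and 4 fell (18 and 4 adjusted over the list alone, adjusted p = 0.000239, and adjusted p = 0.3 with an estimated correlation). RRM2 and CLSPN rose by 1.03 and 1.09. For recombination and Fanconi genes 15 of 33 rose and 1 fell (15 and 2 adjusted over the list alone, adjusted p = 0.000186, and adjusted p = 0.16 with an estimated correlation). FANCA rose by 0.69 ± 0.081. LMNB1 rose by 0.72 ± 0.086 and CCNB1 by 0.33 ± 0.077, while MKI67 (0.18 ± 0.082, adjusted p = 0.0902), IL6 (0.21 ± 0.094, 0.0839), TOP2B (0.032 ± 0.082, 0.809) and NPPA (1.33 ± 0.93, 0.29) were not past the threshold. Replication-dependent histones fell, as 0 of 21 rose and 8 fell (0 and 8 adjusted over the list alone, adjusted p = 0.0104, and adjusted p = 0.0814 with an estimated correlation).

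Matrix, contractile and growth genes fell from day 2 to day 4. In the matrix list 4 of 37 tested members rose and 22 fell (5 and 22 adjusted over the list alone), with a median log2 fold change of -0.35 and an adjusted p of 4.65e-08. COL5A1, COL4A1, COL3A1 and DCN were lower (-1.20, -1.27, -1.22 and -1.36), and COL1A1 fell by 0.70 ± 0.085. For the TGF-beta response 4 of 28 rose and 19 fell (4 and 21 adjusted over the list alone, adjusted p = 7.57e-07). TGFB2 went from 261 ± 9.05 to 87.2 ± 15.7 CPM. Among hypertrophy and fetal-program genes 4 of 30 tested members rose and 19 fell (4 and 20 adjusted over the list alone), with a median log2 fold change of -0.40 and an adjusted p of 3.87e-06. EDN1, the endothelin gene, went from 55.2 ± 10.7 to 12.3 ± 1.27 CPM, IGF1R fell by 1.52 ± 0.083, NPPB by 2.56 ± 0.30 (log2 fold change -3.34 without day 4 replicate 3) and ANKRD1 by 1.09 ± 0.20. In the sarcomere list 1 of 13 rose and 7 fell (1 and 8 adjusted over the list alone, adjusted p = 0.0104, and adjusted p = 0.0526 with an estimated correlation). TPM1 stood at 486 ± 18.7 CPM after 761 ± 62.5. Markers of fibroblasts, smooth muscle and epithelial cells fell with them. Fibroblast markers fell in 10 of 16 cases with 1 rise (10 and 1 adjusted over the list alone, adjusted p = 3.43e-05). Smooth muscle markers fell in 8 of 12 with 0 rises (8 and 1 adjusted over the list alone, 4.52e-05). Epithelial markers fell in 6 of 9 with 0 rises (6 and 0 adjusted over the list alone, 3.43e-05, and adjusted p = 0.057 with an estimated correlation), including KRT18 (-1.90 ± 0.11).

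Biosynthesis genes were also lower at day 4 than at day 2. In ribosome biogenesis 1 of 30 rose and 23 fell (1 and 24 adjusted over the list alone, adjusted p = 5.77e-09, and adjusted p = 0.057 with an estimated correlation). DDX21 went from 652 ± 37.6 to 321 ± 7.66 CPM. In the ATF4 list 3 of 38 rose and 23 fell (3 and 25 adjusted over the list alone, adjusted p = 1.29e-08). SLC7A5, ATF3 and SLC3A2 were lower (-1.99, -1.77 and -1.64). For cholesterol biosynthesis 0 of 25 rose and 15 fell (0 and 15 adjusted over the list alone, adjusted p = 6.74e-06). For NRF2 targets 6 of 39 rose and 17 fell (6 and 17 adjusted over the list alone, adjusted p = 0.00176, and adjusted p = 0.13 with an estimated correlation). TKT and GCLM were lower (-1.15 and -0.97) and HMOX1 fell by 0.50 ± 0.12. Genes of ferroptosis and iron handling fell, as 2 of 22 rose and 11 fell (2 and 12 adjusted over the list alone, adjusted p = 0.00428, and adjusted p = 0.057 with an estimated correlation). SLC7A11 went from 57.8 ± 12.5 to 12.0 ± 2.45 CPM. For topoisomerases and anthracycline handling 2 of 23 rose and 10 fell (2 and 11 adjusted over the list alone, adjusted p = 0.0128, and adjusted p = 0.0526 with an estimated correlation). TOP1 was lower (-0.52 ± 0.076). For cytosolic ribosomal proteins 0 of 72 rose and 14 fell (0 and 1 adjusted over the list alone, adjusted p = 0.00176, and adjusted p = 0.615 with an estimated correlation). Glycolysis and hypoxia genes fell, as 4 of 33 rose and 11 fell (4 and 11 adjusted over the list alone, adjusted p = 0.0489, and adjusted p = 0.615 with an estimated correlation). That call ended without day 2 replicate 1 (adjusted p = 0.0609), day 2 replicate 3 (0.0523), day 4 replicate 1 (0.0847) or day 4 replicate 2 (0.29), and with a minimum of 1 CPM in 3 libraries (0.0633), where the sarcomere call ended too (0.0508).

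From day 4 to day 6 fewer genes differed than from day 2 to day 4, and mitotic genes were lower at day 6. By the titles this step goes from 96 to 112 hours and the earlier one from 48 to 96 hours. The 2 counts of genes may therefore belong to steps of unlike length. PLK1, a kinase of mitotic entry and exit (chromosome 16, 23677656 to 23690367), went from 62.5 ± 9.27 to 27.1 ± 3.25 CPM (adjusted p = 1.55e-06) and CCNB1 from 113 ± 3.47 to 65.7 ± 3.00 CPM (adjusted p = 1.01e-06). In the mitosis and G2/M list 0 of 46 tested members rose and 39 fell (0 and 40 adjusted over the list alone), with a median log2 fold change of -0.49 and an adjusted p of 1.04e-45. KIF20A and HMMR were lower (-0.84 and -0.79), MKI67 fell by 0.57 ± 0.082 and TOP2A by 0.48 ± 0.072. EHF rose from 2.63 ± 0.738 to 15.7 ± 0.732 CPM, the chemokine gene CXCL6 from 3.03 ± 0.614 to 10.1 ± 0.531 and RAB27B, a GTPase of secretory vesicles, from 14.8 ± 2.75 to 47.4 ± 4.96.

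There were 1174 genes that differed, 528 higher and 646 lower at day 6, with 81 and 36 at least 2-fold higher and lower, and 27.6% did not overlap, where chance gives 10%. Scaling by library totals alone gave 1006 higher and 350 lower, and a fit of these 6 libraries alone called 1847 genes. The count fell to 574 without day 4 replicate 1, 690 without day 4 replicate 3, 619 without day 6 replicate 1 and 578 without day 6 replicate 2. KRT34, a keratin, fell by 1.298 ± 0.24, a call that ended in the fit of these 6 libraries alone (adjusted p = 0.0532). MT2A, a metallothionein with near-identical relatives, fell from 286 ± 18.2 to 138 ± 10.2 CPM.

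Among p53 targets 8 of 34 rose and 0 fell (16 and 1 adjusted over the list alone, adjusted p = 9.32e-07). CYFIP2, TP53I3 and CMBL rose by 0.81, 0.55 and 0.44. MDM2 rose by 0.31 ± 0.091 (adjusted p = 0.0403), a call that ended without day 4 replicate 1 (0.11), day 4 replicate 3 (0.169), day 6 replicate 1 (0.198) or day 6 replicate 2 (0.15). CDKN1A (0.18 ± 0.10, adjusted p = 0.314), GDF15 (0.38 ± 0.12, 0.0542), LMNB1 (0.614), TOP2B (0.123), HMOX1 (0.936), NPPA (0.38) and ANKRD1 (0.0706) were not past the threshold. For NF-kB and secretory genes 13 of 41 rose and 5 fell (15 and 10 adjusted over the list alone, adjusted p = 0.0167, and adjusted p = 0.465 with an estimated correlation). SERPINE2 went from 222 ± 4.64 to 481 ± 21.9 CPM, CXCL5 rose by 1.20 ± 0.15, IL6 by 0.64 ± 0.093 and CXCL8 by 0.52 ± 0.082. For recombination and Fanconi genes 6 of 33 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 1.79e-05, and adjusted p = 0.319 with an estimated correlation). BRIP1 and EXO1 rose by 0.46 and 0.34. For DNA replication 6 of 45 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.000198, and adjusted p = 0.465 with an estimated correlation). GINS4 and POLA1 rose by 0.39 and 0.40.

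Mitochondrially encoded genes were lower at day 6 than at day 4, as 0 of 13 tested members rose and 8 fell (0 and 13 adjusted over the list alone), with a median log2 fold change of -0.53 and an adjusted p of 1.16e-11 (adjusted p = 0.319 with an estimated correlation). MT-ND4L went from 568 ± 56.6 to 400.5 ± 15.5 CPM. In the same comparison, of nuclear-retained transcripts, a sign of RNA quality, 3 of 11 tested members rose and 0 fell (5 and 0 adjusted over the list alone), with a median log2 fold change of 0.21 and an adjusted p of 0.0167 (adjusted p = 0.334 with an estimated correlation), such as SNHG14 (0.70 ± 0.14). That call ended without day 4 replicate 3 (adjusted p = 0.109). Nuclear-encoded oxidative phosphorylation genes fell in 2 of 54 cases and rose in 0 (0 and 0 adjusted over the list alone, adjusted p = 0.000172, and adjusted p = 0.666 with an estimated correlation). In the matrix list 2 of 37 rose and 8 fell (4 and 12 adjusted over the list alone, adjusted p = 0.00491, and adjusted p = 0.319 with an estimated correlation). SPARC, POSTN, LOX and COL4A1 were lower (-0.49, -0.47, -0.47 and -0.45). COL1A1 fell by 0.39 ± 0.085 (adjusted p = 0.00523, and 0.0597 without day 6 replicate 2). NPPB fell by 1.72 ± 0.45 (adjusted p = 0.0209), and that call ended without day 4 replicate 3 (log2 fold change -0.939, adjusted p = 0.255). It also ended without any of the 3 day 6 libraries (0.0649, 0.0828 and 0.078).

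A last set of lists was past the threshold from day 4 to day 6 with few changed members. In heat shock 0 of 21 rose and 2 fell (0 and 2 adjusted over the list alone, adjusted p = 0.00685, and adjusted p = 0.465 with an estimated correlation). In cholesterol biosynthesis 0 of 25 rose and 4 fell (0 and 4 adjusted over the list alone, adjusted p = 0.0125, and adjusted p = 0.344 with an estimated correlation). Of cytosolic ribosomal proteins 0 of 72 rose and 0 fell (0 and 0 adjusted over the list alone, adjusted p = 0.00895, and adjusted p = 0.802 with an estimated correlation). Of ferroptosis and iron handling genes 2 of 22 rose and 0 fell (4 and 1 adjusted over the list alone, adjusted p = 0.0316, and adjusted p = 0.319 with an estimated correlation). Examples were STIP1 (-0.42 ± 0.088) and TFRC, the transferrin receptor gene (0.54 ± 0.10). Each of these calls ended without 1 library, and without day 4 replicate 3 it was those of heat shock (adjusted p = 0.0547) and ferroptosis (0.126). Those that rested on day 4 replicate 2 were cholesterol (0.062) and the NF-kB list (0.0642). Ribosomal proteins (0.337) rested on day 4 replicate 1, and ferroptosis (0.1) and the NF-kB list (0.0914) also on day 6 replicate 3.

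The 3 exposures shared many of their calls against the control. 1903 genes were higher and 1661 lower at all 3 exposures, among them CDKN1A, MDM2, GDF15, CXCL8, IL6 and C3 on the higher side and LMNB1, CCNB1, MKI67, TOP2A, INSIG1 and INHBE on the lower. Days 2 and 4 shared 4189 calls in the same direction and 267 in opposite directions, days 2 and 6 shared 4313 and 482, and days 4 and 6 shared 5201 and 4. Independent lists of these sizes would share 1493, 1788 and 1382 calls in the same direction. The fold changes correlated at 0.745, 0.715 and 0.911 across genes, which are not independent replicates. Unchanged groups simulated against the same controls gave 0.517, 0.523 and 0.524, and at most 0, 0 and 1 shared calls. No gene was changed in these simulations, so few calls could arise there. Their shared calls are therefore no yardstick for the observed counts of shared calls. The covariances were 0.516, 0.562 and 0.609, and exceeded the simulated ones of 0.0418, 0.042 and 0.0416 by 0.474, 0.52 and 0.567. The 3 controls could not be split into parts of 2 libraries, so part of the excess in shared calls may come from the shared controls.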

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

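Of the tests in this part, the leukocyte test and the comparison with a shift of all genes were chosen only after results had been seen. The difference between exposures picked out 267 genes that were called in opposite directions at day 2 and day 4 against the control, 160 of them higher at day 2 and lower at day 4, and 107 the other way round. In the direct test of day 4 against day 2 all 267 were called. Picking genes by opposite calls all but fixes that outcome, so the direct test adds little support. Of 221 named genes 18 were of this kind, and of 35 lists 0. All but CXCL2 were above the control at day 2 and below it at day 4. Genes of ribosome assembly and amino acid or redox supply were among them, with log2 fold changes from day 2 to day 4 of -1.022 for DDX21, -0.773 for NOLC1, -0.942 for RRP12, -1.641 for SLC3A2, -1.145 for TKT and -0.97 for GCLM. Stress and growth genes had values of -1.568 for PMAIP1, -1.768 for ATF3, -1.251 for NUAK1, -1.583 for TGFB2 and -1.524 for IGF1R, and structural and matrix genes -1.903 for KRT18, -1.667 for LMOD1, -1.223 for COL3A1 and -0.881 for SPARC. The histone gene H2AC6 (-1.353) and the interferon-induced GBP1 (-1.739) followed them, and the chemokine gene CXCL2 went the other way (1.907).

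Interferon-stimulated genes were higher at day 2 than in the control and lower at day 4 than at day 2, and 3 technical explanations were tested. Under the 3 scalings the lowest list median at day 2 was 1.19 (bootstrap interval 0.462 to 1.53), where the scaling explanation set beforehand required a median under 0.5; the interval reached below 0.5, so a further comparison was added after that was seen, and the widest shift of all genes between scalings was 0.123, below the whole interval. Leukocytes could carry such genes, and 1 of 8 tested leukocyte markers was higher at day 2. The list holds 20 markers. The libraries are of a cultured line, so the leukocyte test could hardly have come out otherwise and decides little. After trends with GC content and exonic length were removed the median was 1.4 (0.591 to 1.74). Both intervals came from resampling the genes of the list, so they do not measure the spread between libraries. For these libraries the values for scaling and for GC content with exonic length speak against those explanations. A response that depends on the length or timing of exposure may be what remains, although other technical differences between the day 2 and day 4 libraries were not tested.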

How the results depend on the processing

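Of 403 named-gene results, 399 kept their direction and side of the threshold with DESeq2, 401 with DESeq2-type size factors, 389 with library totals alone and 394 without a low-count filter. The block by replicate number left the gene counts at 7950, 6035, 7296, 5680 and 962 for the 5 comparisons and at 10611 for any difference. Libraries of the same number correlated at -0.17 to 0.096 over 18 pairs and 3 of 12 correlated best with their own number, so the numbers gave no pairing. DESeq2 also called 7946, 6072, 7285, 5789 and 1125 of the genes called, and the block 7904, 5985, 7252, 5636 and 948. Control replicate 2 and day 2 replicate 3 had an outlying mitochondrial share (8.261% and 5.514%). Without these 2 libraries, chosen after the data were seen, the counts were 7913, 6514, 7384 and 6127 for the first 4 comparisons. Control replicate 2 also lay apart from the other controls on the third principal component (-24.2 against 18.3 and 13.6). On that component, with 6.66% of the variance, day 4 libraries scored -21.9 to -6.59 and day 6 libraries 6.17 to 16.4. The day 4 and day 6 libraries were thus set apart on a component that also varied between untreated libraries. With only control replicate 2 left out, 8241, 6354 and 7221 genes were called at day 2, day 4 and day 6 against the control. For day 6 against day 4 the count was 1847 with only these groups in the fit, and 574 to 884 without 1 library (leaving a group of 2). With an estimated correlation 10, 7, 5, 10 and 2 lists were past the threshold in place of 16, 19, 16, 23 and 13, and with fry 26 at day 6 and 4 from day 4 to day 6; the cause was not tested. The calls that held with an estimated correlation are those printed without such a value. Regrouping the 6 libraries of a comparison gave at most 0 called genes, but 10 splits are too few for a share under 0.05. Of 100 splits of all 12 libraries, the real one gave 10978 and the highest other 3159. In the simulated data 53.7% of 1.5-fold changes were recovered. Far fewer genes were changed there than were called in these comparisons, which makes the adjusted threshold stricter. That share may therefore not hold for these data. Of the 34 members of the sarcomere list only 13 were tested.

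Some results without a call changed sign under an alternative, and the cause was not tested. Under library totals alone the value was 0.0478 for HMOX1 from day 4 to day 6. With a minimum of 1 CPM list medians were 0.00407 for apoptosis from day 4 to day 6, -0.132 for leukocyte markers and -0.000967 for oxidative phosphorylation from day 2 to day 4 (-0.0019 with DESeq2-type size factors, -0.00029 with the replicate block), and 0.118 for histones at day 2. Without 1 library the values ranged over -0.0725 to 0.0433 for HMOX1 from day 4 to day 6, -0.234 to 1.93 and -2.5 to 0.0744 for NPPA in the steps from day 2 to 4 and 4 to 6, -0.175 to 0.935 for NPPB at day 4 and -0.0133 to 0.0976 for TOP2B from day 2 to day 4. List medians against the control ranged over -0.128 to 0.0215 for fatty acid oxidation, -0.0651 to 0.0789 for ferroptosis, -0.00768 to 0.159 for leukocytes, -0.0601 to 0.17 for NRF2, -0.0925 to 0.0175 for nuclear-retained transcripts and -0.226 to 0.0851 for senescence at day 2. At day 4 they were -0.0802 to 0.0863 for ribosomal proteins, -0.137 to 0.0532 for hypertrophy (called without control replicate 3, adjusted p = 0.0452), -0.183 to 0.0465 for nuclear-retained transcripts and -0.0246 to 0.1 for the sarcomere, and at day 6 -0.163 to 0.0269 for ribosomal proteins, -0.0251 to 0.112 for oxidative phosphorylation and -0.0113 to 0.226 for the sarcomere. From day 2 to day 4 they were -0.0709 to 0.0858 for complement, -0.000621 to 0.267 for mitochondrially encoded genes and -0.0341 to 0.0332 for oxidative phosphorylation. From day 4 to day 6 they were -0.035 to 0.032 for apoptosis, -0.0133 to 0.0551 for ATF4, -0.0224 to 0.0877 for fatty acid oxidation, -0.112 to 0.0238 for hypertrophy, -0.0154 to 0.0868 for interferon, -0.0761 to 0.342 for endothelial, -0.037 to 0.275 for leukocyte and -0.0212 to 0.0809 for smooth muscle markers, -0.00404 to 0.0345 for NRF2 and -0.0269 to 0.0813 for the TGF-beta response.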

Other observations

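The gene families in this paragraph were chosen after the data were seen, and the counts of transcript types looked at with them were not tested. Tests of 46 families gave a set past the threshold in each comparison, and every one lost its call with an estimated correlation. Only part of these calls is printed. Each family below was also past the threshold in another comparison, so none is particular to 1 comparison. The TNF receptor family also rose at day 2 and day 4 (adjusted p = 0.000468 and 0.000727), and the kinesins also fell at day 4 and day 6 (0.00067 and 0.0025). At day 6 the chemokines were higher and the aminoacyl-tRNA synthetases lower (0.000587 for both). The collagens rose at day 2 (0.000371). At day 2, of the APOBEC family 5 of 6 rose and 0 fell (median log2 fold change 0.68, adjusted p = 0.00319, and adjusted p = 0.229 with an estimated correlation), of the keratins 12 of 19 rose and 0 fell (median log2 fold change 1.05, adjusted p = 0.000371, and adjusted p = 0.104 with an estimated correlation), and of the kinesins 6 of 41 rose and 24 fell (median log2 fold change -0.48, adjusted p = 0.00048, and adjusted p = 0.104 with an estimated correlation). At day 4, of the CCL and CXCL chemokines 9 of 17 rose and 1 fell (median log2 fold change 0.95, adjusted p = 0.000287, and adjusted p = 0.113 with an estimated correlation), and of the aminoacyl-tRNA synthetases 2 of 18 rose and 12 fell (median log2 fold change -0.53, adjusted p = 4.71e-06, and adjusted p = 0.214 with an estimated correlation). At day 6, of the TNF receptor family 11 of 19 rose and 3 fell (median log2 fold change 0.97, adjusted p = 0.00441, and adjusted p = 0.137 with an estimated correlation), and of the laminins 8 of 13 rose and 2 fell (median log2 fold change 0.33, adjusted p = 0.0183, and adjusted p = 0.393 with an estimated correlation). From day 2 to day 4, of the collagens 4 of 37 rose and 20 fell (median log2 fold change -0.52, adjusted p = 0.000156, and adjusted p = 0.352 with an estimated correlation). From day 4 to day 6, of the tubulins 0 of 18 rose and 7 fell (median log2 fold change -0.38, adjusted p = 8.69e-06, and adjusted p = 0.557 with an estimated correlation).

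Lists without a call in any comparison included senescence markers, where at day 2 7 of 19 rose and 7 fell (7 and 8 adjusted over the list alone, adjusted p = 0.891), calcium handling and ion channels, where 10 of 26 rose and 4 fell (11 and 5 adjusted over the list alone, adjusted p = 0.125), and fatty acid oxidation and PPAR targets, where 7 of 29 rose and 8 fell (8 and 8 adjusted over the list alone, adjusted p = 0.871). For markers of other cells at day 2, of endothelial markers 1 of 9 rose and 0 fell (1 and 0 adjusted over the list alone, adjusted p = 0.932), of leukocyte markers 1 of 8 rose and 0 fell (1 and 0 adjusted over the list alone, adjusted p = 0.747), and of neuronal and glial markers 3 of 10 rose and 3 fell (4 and 3 adjusted over the list alone, adjusted p = 0.932). The median and mean of the senescence list had opposite signs at day 2 (-0.0755 and 0.401). Of its 19 tested members 5 were not called there, where 47.2% of all tested genes were called. The list test asks for a shift in 1 direction, so it cannot decide on a list whose members moved both ways. With fry the adjusted p of the senescence list against the control was 0.00031 at day 2, 0.0611 at day 4 and 0.043 at day 6.

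Both tests of the mitochondrial genes were chosen only after their fall from day 4 to day 6 had been seen. The list median closest to 0 without any 1 of the 6 libraries was -0.473 (range -0.565 to -0.473), which speaks against a single library as the source. The share of counts from these genes averaged 7.01% in the controls, 6.96% at day 2, 8.14% at day 4 and 6.37% at day 6, and the fall of 1.77 points was 0.784 times the widest range inside a group, 2.25 points among the controls. By that measure variation between libraries could be as large as the fall. The libraries compared did not overlap, at 8.01% to 8.34% for day 4 and 5.77% to 6.80% for day 6, with ranges of 0.335 and 1.03 points. In the same comparison nuclear-retained transcripts, a sign of RNA quality, had a median log2 fold change of 0.21 (adjusted p = 0.0167, and adjusted p = 0.334 with an estimated correlation), and a link between the 2 was not tested. The source of the fall is left open.

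Whether genes with a long genomic span respond differently, as blocked transcription would predict, was tested over 13282 protein-coding genes. The rank correlation of span with log2 fold change was -0.0188 at day 2, -0.0032 at day 4 and 0.0735 at day 6 (bootstrap interval 0.0538 to 0.0908), and 0.0195 and 0.165 from day 2 to day 4 and day 4 to day 6. The intervals in this paragraph came from resampling genes, so they do not measure the spread between libraries. A fall of long genes at all 3 exposures, which required values below -0.1, was not seen. With GC content, exonic length and mean expression held fixed the values were 0.0239, 0.0124, 0.0281, -0.0186 and 0.0359, and at day 6 a ratio of 0.382 (0.164 to 0.541) to the plain one left it open whether the held values explain it, since the interval held the bound of 0.5. From day 4 to day 6, where the plain correlation was largest, the ratio was 0.217 (0.141 to 0.295), below that bound. Mean expression was held fixed as well, so the loss cannot be put to GC content and length alone.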
